A study of Mus musculus with 15 samples.

How the data were processed

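Endothelial cells, which line blood vessels, were collected from the brain, heart and liver of Tie2-GFP mice on the FVB background, in which the promoter of the endothelial receptor gene Tek (Tie2) drives green fluorescent protein. Per the labels' protocols the mice were 8 to 12 weeks old, large vessels were removed, the tissue was digested with enzymes and the GFP-positive cells were sorted directly into lysis buffer. Each of the 5 brain samples was a pool of 6 mice, each of the 5 heart samples a pool of 4 mice and each of the 5 liver samples a pool of 2 mice, with males and females in equal number. The digestion lasted 60 min in every tissue but differed otherwise. Brain was digested with collagenase and DNase at 37 °C, spun through albumin and treated briefly with trypsin. Heart was digested with collagenase at 37 °C. Liver was digested with dispase at room temperature, after which a slow spin removed hepatocytes and a Percoll gradient followed. Tissue, enzyme, digestion temperature and pool size therefore cannot be told apart in this design. From each sample 5 ng of total RNA was amplified to sense cDNA, labelled with biotin and hybridised to an Affymetrix mouse gene array, which reads transcripts with probes spread along their whole length.

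The authors deposited log2 values for 35556 probe sets on 15 arrays. Per the submitters' processing notes these values were made by RMA (background correction, quantile normalization and a robust summary of the probes of a probe set) with Affymetrix Power Tools. Versions and the genome build behind the probe sets are not given in the sources used here, so no coordinates are printed. The values were used as deposited. RMA forces the arrays to nearly equal distributions and compresses large differences, so folds computed as powers of 2 of log2 differences are likely to be smaller than the differences in RNA. The scanner files were not used here, so no test of signal against the array's own background probes was made. The precision of each mean is limited by the number of arrays, 5 per tissue.

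GEO's annotation of the array listed 23410 of the probe sets. Of these, 21789 carried 1 gene symbol and 1621 carried several; the other 12146 probe sets of the file are unnamed here. Of the probe sets with 1 symbol, 21698 matched a current RefSeq gene (table for the mouse assembly GRCm38.p6, used for names only), and no symbol changed. Probe sets with several symbols or no name were left out of the comparisons. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 15 arrays was kept, which gave 19938 genes. Genes with close relatives, such as Slco1a4, Serpina1c, Mt1 and Mt2, Akr1b8, Fabp4 and Fabp9 and the H2 genes, are uncertain to the extent that probes of one family member bind RNA of another.

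One linear model with a mean per tissue was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the 3 tissues share 1 estimate of the spread of each gene. It had 12 residual degrees of freedom and 4.75 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes within each of the 3 pairwise contrasts, with a threshold of 0.05. Adjusted p-values given for genes below come from this fit. A gene was called enriched in a tissue when it was higher than in both other tissues, with both adjusted p-values under the threshold and both log2 differences at least 1, and depleted when it was lower than in both by the same rule. Where a gene has a single difference below, it is the difference from whichever of the other tissues lay nearer. Values are means ± SD over 5 arrays, and differences carry the standard error (SE) of the model.

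Before the data were examined, 36 gene lists were fixed from general knowledge. Of these, 22 cover endothelial functions and cell states: pan-endothelial genes, blood-brain barrier transporters, tight junctions, Wnt and norrin signalling, fatty acid uptake, fatty acid oxidation, glycolysis, the respiratory chain, sinusoidal endocytosis, sinusoidal identity, haemostasis, caveolae and diaphragms, leukocyte adhesion, Notch and arterial genes, venous and lymphatic genes, VEGF and angiopoietin signalling, transcription factors, basement membrane, antigen presentation, interferon response, immediate-early and heat shock genes, and proliferation. The other 14 hold markers of neurons, astrocytes, oligodendrocytes, pericytes and smooth muscle, macrophages, Kupffer cells, hepatocytes, stellate cells, cardiomyocytes, fibroblasts, lymphoid cells, granulocytes, red cells and platelets. Together they name 543 genes, of which 509 were measured. Each list was tested with limma's camera, which asks whether a list's genes shift more than the other genes between a tissue and the mean of the other two, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists within a tissue. Beside the test stands the number of members higher or lower than in both other tissues, adjusted over all genes and adjusted over the list alone; where only the first is given below, the second was the same. Because camera compares with the mean of 2 tissues, a list can be lower in one of them merely because it is high in another; the member counts show this.

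Genes named in the text were chosen by a rule set before the data were examined. It takes, per tissue, the 12 enriched and 6 depleted genes with the largest difference from the nearer tissue among genes whose 5 arrays all lay beyond the 10 others, leaving out predicted genes and olfactory or vomeronasal receptors. It adds up to 4 members of each list described, those with the largest difference between that tissue and the mean of the other two, and the 3 largest differences in each direction of each pairwise comparison. Tek, Pecam1, Cdh5, Meox2, Tcf15, Gata4, Lef1 and Foxq1 are always given. Among list members, those whose call ended when a single array was left out were mostly not described.

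The fit was tested on simulated arrays with the means and spreads of the real genes. For the enriched and depleted calls over 19938 genes, 94% of 50 genes changed by a log2 difference of 1.25 were recovered, 100% of 50 changed by 2 and 98% of 50 changed by 3, and 0% of 50 changed by 0.5, which lies under the fold limit; 0 unchanged genes were called. In a simulated heart shift of 0.5 in the 12 measured glycolysis genes, camera called that list and 0 of the others. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.815 (Kupffer cell markers). This check therefore does not show how often camera calls a list of correlated genes without a shift. Alternatives to each choice were also computed: centring each array on its median or on the 28 pan-endothelial genes, a new quantile normalization, a filter on dim genes (10982 genes kept), the mean of a gene's probe sets, a trended and robust variance model, array weights, the replicate number as a block, leaving out each array in turn, other thresholds, camera with an estimated correlation, and fry. Fry asks whether a list's genes move, on balance, in one direction, without comparing them with other genes. Alternatives that leave out several arrays, or the members of the other-cell lists, were added after seeing the data.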

Results

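Gene expression was measured on 15 arrays of freshly sorted microvascular endothelial cells, 5 each from brain, heart and liver, to find the genes that set each of the 3 endothelia apart from the other two. The arrays had similar overall levels, with medians over the 19938 genes between 5.98 and 6.11 on the log2 scale. Arrays of the same tissue correlated with each other across genes at r = 0.978 to 0.993. Across tissues r was 0.948 to 0.960 for brain with heart, 0.918 to 0.929 for brain with liver and 0.922 to 0.945 for heart with liver; these are correlations across genes, which are not independent replicates. The first principal component, with 53.2% of the variance, separated liver from the other tissues, and the second, with 24.6%, separated brain from heart. The third held 4.24%. On it replicate 1 had the lowest score in brain (-11.5), heart (-26.0) and liver (-17.3) and replicate 5 the highest (7.88, 16.3 and 19.2).

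**Figure D1:**
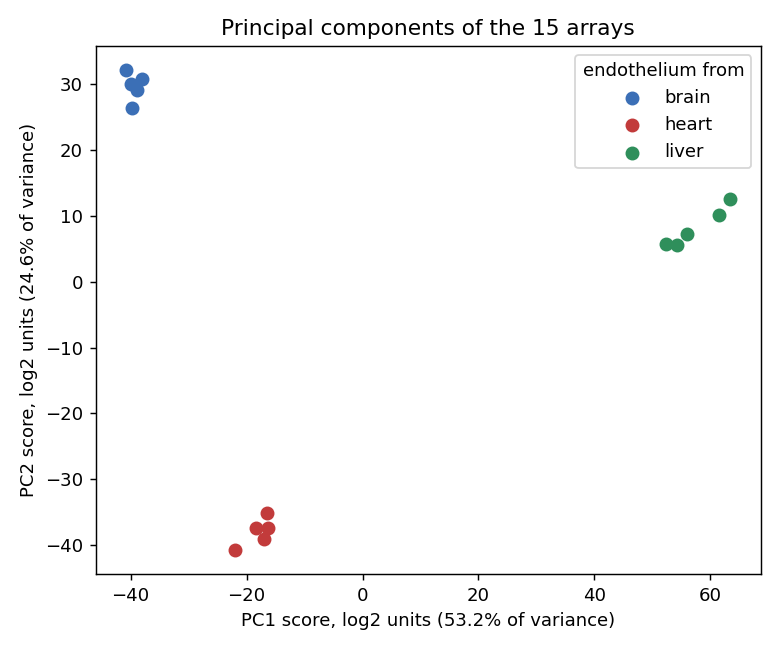
Scores of the 15 arrays on the first 2 principal components of the log2 values of 19938 genes, in log2 units; each point is an array and its colour is the tissue. Liver arrays lie between 52.3 and 63.4 on the first component and all brain and heart arrays below -16, while on the second the brain arrays lie above 26 and the heart arrays below -35.

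All 3 groups carried high levels of endothelial genes. Tek, the gene whose promoter drives the GFP used for sorting, had log2 values of 11.50 ± 0.13 in brain, 11.02 ± 0.04 in heart and 11.32 ± 0.08 in liver (SD, n = 5 each). Heart was lower than brain by a log2 difference of 0.48 (SE 0.07) and lower than liver by 0.30 (SE 0.07), with adjusted p-values of 0.000107 and 0.00428; brain minus liver was 0.18 (adjusted p = 0.0868). Without brain replicate 4 liver differed from brain by -0.23 (adjusted p = 0.0214). Pecam1, an adhesion molecule of endothelial junctions, was 11.27 ± 0.09, 11.36 ± 0.09 and 10.97 ± 0.13 in the same order and was lower in liver than in both others (adjusted p-values 0.00888 and 0.00108). That call ended when arrays were centred on the pan-endothelial list, with a difference of -0.13 and adjusted p = 0.214. Cdh5, the cadherin of endothelial junctions, was 11.50 ± 0.11, 12.06 ± 0.17 and 11.73 ± 0.26. Heart exceeded liver by 0.33 (SE 0.12, adjusted p = 0.0436), a call that was lost when most of the single arrays were left out, for example without heart replicate 2 (0.27, adjusted p = 0.117). The pan-endothelial list of 28 genes averaged 10.25 ± 0.11 in brain, 10.26 ± 0.06 in heart and 10.09 ± 0.09 in liver and did not pass the list test in any tissue (smallest adjusted p = 0.118). Its members were not all alike between tissues. In liver 8 of the 28 were lower than in both others and 5 higher (10 and 5 adjusted over the list alone). Fry called the list in brain (adjusted p = 0.0338) and in liver (adjusted p = 0.00404).

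Brain endothelium was marked by transporters of the blood-brain barrier and by genes of Wnt and norrin signalling, and several fatty acid uptake genes were lower there than in the other tissues. In brain, 311 genes were enriched and 130 depleted. The leading gene was Slco1c1 (probe set 10542596), a carrier of thyroid hormone, at 12.06 ± 0.04 in brain against 5.195 ± 0.21 in heart and 4.70 ± 0.18 in liver, a 117-fold difference from the nearer tissue (log2 6.87, SE 0.10, adjusted p = 1.84e-17). The organic anion carrier Slco1a4 was 116-fold higher, the lipid transporter Mfsd2a 55.5-fold, the glucose transporter Slc2a1 45.2-fold and the organic anion transporter Slc22a8 41.6-fold. Also among the 12 leading genes were Sema3c, a guidance factor (65.8-fold), the growth factor Ptn (51.9-fold), Ccdc141 (45-fold), Gkn3 (38.9-fold), the tight junction protein Ocln (34.9-fold), Itm2a (34.3-fold) and the peptidoglycan recognition protein Pglyrp1 (31.4-fold).

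Of 24 measured barrier transporters, 23 were higher in brain than in both other tissues and 21 were enriched, with 0 lower; adjusted over the list alone the count was also 23. The list's mean was 10.6 ± 0.14 in brain, 6.97 ± 0.13 in heart and 6.46 ± 0.06 in liver (camera adjusted p = 4.74e-55, and 2.09e-05 with an estimated correlation). Of 16 Wnt and norrin signalling genes, 12 were higher in brain and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 4.88e-17). Among them the Wnt effector Lef1 was at 10.92 ± 0.15 in brain against 5.96 ± 0.19 and 5.88 ± 0.28 in heart and liver, 31.1-fold over heart, with Apcdd1 26.9-fold, Reck 10.7-fold and the forkhead factor Foxf2 11.3-fold higher than in the nearer tissue. Foxq1, another forkhead factor of the list, was 1.97-fold higher (7.33 ± 0.49 in brain). The tight junction list was mixed. Of 14 members, 6 were higher in brain and 2 lower (6 and 3 adjusted over the list alone), its median difference was 0.12 and its mean 0.98, and camera called it higher (adjusted p = 0.000891, and 0.0316 with an estimated correlation). Its largest differences were those of Ocln, Marveld2 (10.7-fold), Lsr (5.08-fold) and Cgnl1 (2.22-fold).

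The fatty acid uptake list was lower in brain (camera adjusted p = 4.55e-05, 0.0316 with an estimated correlation), with 6 of 24 members lower than in both tissues and 2 higher (8 and 2 adjusted over the list alone). Of the 6 leading depleted genes of brain, 4 belong to this group. The fatty acid receptor Cd36 was at 4.13 ± 0.38 in brain, 12.37 ± 0.13 in heart and 11.30 ± 0.14 in liver, 144-fold below the nearer tissue (adjusted p = 9.18e-17 against liver). Gpihbp1, which carries lipoprotein lipase to the vessel lumen, was 21.3-fold lower, and the fatty acid binding proteins Fabp4 and Fabp5 were 18.3-fold and 17.3-fold lower. The water channel Aqp1 was 28.6-fold and Car8 26.9-fold lower. Fatty acid oxidation genes were higher in brain (6 of 16 higher, 0 lower; camera adjusted p = 0.000925), a call lost with an estimated correlation (adjusted p = 0.212).

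Of 21 Notch and arterial genes, 6 were higher in brain and 1 lower, among them Gkn3 and the arterial kinase Bmx (5.21-fold); the list's camera adjusted p was 7.01e-06, and 0.212 with an estimated correlation. Stmn2, also on the list, was 8.79 ± 0.17 in brain and 8.98 ± 0.31 in heart (adjusted p = 0.553). Leukocyte adhesion genes (2 of 11 higher, camera adjusted p = 0.0393) and interferon response genes (4 of 17 higher and 1 lower, 6 and 1 adjusted over the list alone, camera adjusted p = 0.0479) lost their calls with an estimated correlation, at adjusted p = 0.212 and adjusted p = 0.39. Proliferation genes were lower in brain (5 of 17 lower and 0 higher, 7 and 0 adjusted over the list alone, camera adjusted p = 1.32e-05; adjusted p = 0.281 with an estimated correlation), and so were antigen presentation genes (2 of 12 lower, camera adjusted p = 0.00283; adjusted p = 0.109 with an estimated correlation). Markers of neurons, astrocytes and oligodendrocytes did not pass the list test in brain (adjusted p-values of 0.218, 0.209 and 0.485). Of these markers 0 of 13, 2 of 13 and 1 of 10 were higher in brain, and 1 astrocyte marker was lower. Adjusted over the astrocyte list alone, 4 were higher and 1 lower. The pericyte and smooth muscle markers averaged 6.67 ± 0.67 in brain, with brain replicate 1 the highest at 7.73. The hepatocyte protein Ttr, a carrier of thyroid hormone that is also made by the choroid plexus, was at 12.48 ± 0.30 in brain, 5.33 ± 0.28 in heart and 8.44 ± 0.87 in liver and had the largest difference of brain over heart.

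Heart endothelium was marked by genes of fatty acid uptake, by the transcription factors Meox2 and Tcf15 and by caveolar genes, and its arrays also held transcripts of cardiomyocytes. In heart, 181 genes were enriched and 62 depleted. The glycerol channel Aqp7 (probe set 10512145) was at 10.54 ± 0.21 in heart against 5.01 ± 0.19 in brain and 5.16 ± 0.10 in liver, 41.7-fold higher (log2 5.38, SE 0.11, adjusted p = 1.72e-16). The homeobox factor Meox2 (probe set 10395409) was at 9.24 ± 0.05 in heart against 4.13 ± 0.21 and 4.29 ± 0.19, 30.9-fold higher (log2 4.95, SE 0.10, adjusted p = 3.33e-16). Lipoprotein lipase, Lpl, was 23.5-fold higher, the metalloproteinase inhibitor Timp4 21.6-fold, the retinol binding protein Rbp7 18.8-fold, Ablim3 17.3-fold and C1qtnf9 15.3-fold. Timp4 followed the cardiomyocyte markers over the heart arrays (slope 0.69), as did the fibroblast marker Dpt (1.88) and the pericyte marker Pdgfrb (0.99). RNA from cardiomyocytes, or from other cells whose markers moved with theirs, therefore stays open as the source of Timp4. The same holds for Fabp9 (slope 2.10), which was 12.1-fold higher but uneven, at 7.65 ± 1.90 in heart, and it is a close relative of Fabp4, which was at 12.49 ± 0.09 there. The other 4 of the 12 leading genes were sarcomere genes on the cardiomyocyte list: Myl2 (66.2-fold), Tnnt2 (33.7-fold), Actc1 (22.1-fold) and Tnnc1 (15.5-fold).

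Of 24 fatty acid uptake genes, 9 were higher in heart than in both other tissues and 7 enriched, with 0 lower; the count adjusted over the list alone was also 9. The list's mean was 8.38 ± 0.13 in heart, 7.44 ± 0.04 in liver and 6.62 ± 0.09 in brain (camera adjusted p = 5.23e-08, 0.0049 with an estimated correlation). Beside Aqp7 and Lpl, the nuclear receptor Pparg was 10.8-fold and Cd36 was 2.10-fold higher than in the nearer tissue. Enriched Fabp3, named after its slope was seen, followed the cardiomyocyte markers (slope 1.92), so RNA of cardiomyocytes or other cells stays open as its source. The slopes of Pparg (0.29), Lpl (0.09), Cd36 (-0.03) and Aqp7 (-0.14) were lower. Without heart replicates 1 and 3 the list was still called (mean difference 1.26 against 1.35, camera adjusted p = 8.45e-07). Of 9 genes of caveolae and diaphragms, 4 were higher in heart and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 7.94e-09, 0.000488 with an estimated correlation). The caveolar coat gene Cav1 was 2.14-fold higher at 11.65 ± 0.07, Ehd2 2.59-fold and Cav2 1.66-fold higher. Aqp1 of the same list lay between the other two tissues, at 10.92 ± 0.20. The transcription factor list as a whole did not pass in heart (camera adjusted p = 0.292), with 8 of 29 members higher and 1 lower (9 and 1 adjusted over the list alone). Its members Meox2, Tcf15 (4.39-fold, 9.06 ± 0.42 in heart, adjusted p = 1.09e-07) and Meox1 (2.32-fold) were enriched. Of 16 basement membrane genes 7 were higher and 0 lower (camera adjusted p = 2.03e-07), a call lost with an estimated correlation (adjusted p = 0.0877). Its members included Lamb1 (5.73-fold), Lamc1 (1.57-fold) and Hspg2 (1.50-fold), while Sparcl1 was 12.81 ± 0.06 in heart and 12.76 ± 0.07 in brain (adjusted p = 0.955).

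Genes depleted in heart included the iron exporter Slc40a1, at 4.82 ± 0.19 against 10.003 ± 0.27 in brain and 10.37 ± 0.18 in liver, 36.5-fold lower (adjusted p = 5.73e-15 against brain). The metallothioneins Mt2 and Mt1 were 28.2-fold and 7.84-fold lower, with SDs of 1.33 and 0.85 among the heart arrays. Gatm, which makes the precursor of creatine, was 27.7-fold lower, the metal ion importer Slc39a8 12.7-fold lower and Ttr 8.68-fold lower. Notch and arterial genes were higher in heart by camera (2 of 21 higher and 0 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.000373) and lost the call with an estimated correlation (adjusted p = 0.331). Fatty acid oxidation genes (3 of 16 lower and 0 higher, 5 and 1 adjusted over the list alone, camera adjusted p = 0.00112) and respiratory chain genes (0 of 20 higher or lower than in both, camera adjusted p = 0.00858) were lower, with adjusted p = 0.209 and adjusted p = 0.502 with an estimated correlation. Proliferation genes were called higher (camera adjusted p = 0.0103), although 0 of 17 members passed against both tissues. That call was lost with an estimated correlation (adjusted p = 0.575) and without heart replicate 2 (adjusted p = 0.0669). Its members with the largest differences were Top2a at 6.48 ± 0.69 in heart, 5.87 ± 0.58 in liver and 4.56 ± 0.17 in brain, and Mki67 at 6.25 ± 0.60, 5.84 ± 0.37 and 5.03 ± 0.21. Top2a did pass against both tissues without heart replicate 3 (0.80 over liver, adjusted p = 0.0474) and without liver replicate 3 (0.84, adjusted p = 0.027).

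Markers of other cell types moved with the heart group. Of 16 cardiomyocyte markers, 15 were higher in heart than in both other tissues and 11 enriched (16 higher adjusted over the list alone; camera adjusted p = 3.8e-17, and adjusted p = 0.0652 with an estimated correlation). Their mean was 8.28 ± 0.67 in heart against 5.94 ± 0.08 in brain and 5.71 ± 0.10 in liver, and the heart arrays ranged from 7.63 in replicate 4 to 9.12 in replicate 1. Of 11 fibroblast markers 5 were higher (6 adjusted over the list alone; camera adjusted p = 6.54e-07, and adjusted p = 0.0685 with an estimated correlation). Dpt was at 7.81 ± 1.54, Postn at 6.74 ± 0.82 and Lum at 5.79 ± 0.71 in heart. Of 14 pericyte and smooth muscle markers 3 were higher (camera adjusted p = 0.000429, and adjusted p = 0.502 with an estimated correlation), with a mean of 7.18 ± 0.48 in heart. Without heart replicates 1 and 3, whose cardiomyocyte markers were highest, 158 genes were enriched, of which 145 were also among the 181, and 9 cardiomyocyte markers were enriched, against 11 with all arrays.

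Liver endothelium was the most distinct of the 3 by count and was marked by genes of the sinusoid, the wide and permeable capillary of the liver that clears particles and proteins from blood. In liver, 536 genes were enriched and 292 depleted. The lectin Clec4g (probe set 10576774) was at 12.54 ± 0.07 in liver against 5.14 ± 0.25 in brain and 5.12 ± 0.15 in heart, a 169-fold difference (log2 7.40, SE 0.11, adjusted p = 1.39e-18). The nuclease Dnase1l3 was 149-fold higher, the scavenger receptor Msr1 139-fold, the mannose receptor Mrc1 137-fold and the cytokine Il1a 133-fold. The prostaglandin-degrading enzyme Hpgd was 99.7-fold, Plxnc1 86.8-fold, the hyaluronan receptor Stab2 78.8-fold, the transcription factor Tfec 65.6-fold, the Fc receptor Fcgr2b 60.7-fold, Akr1b8 57.5-fold and coagulation factor F8 50.4-fold higher.

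**Figure D2:**
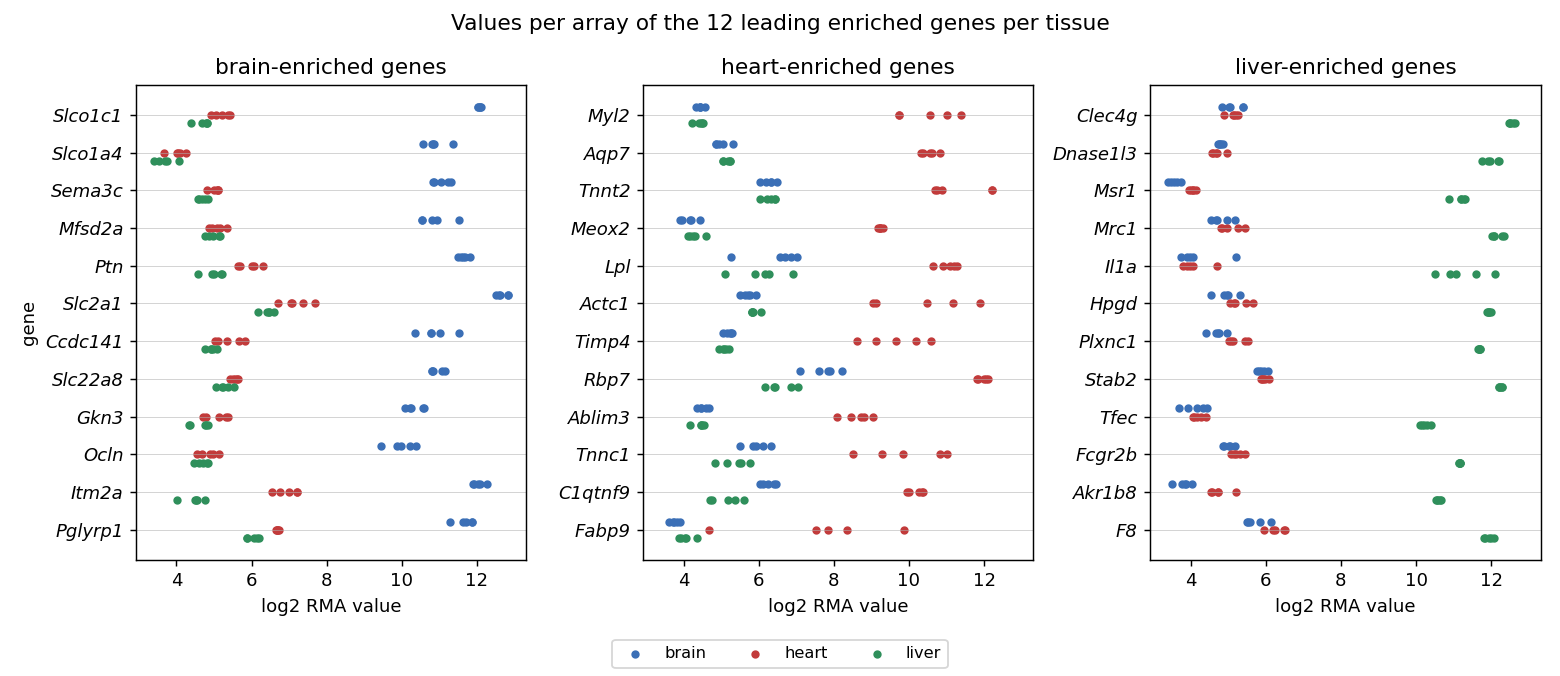
Log2 RMA values on every array (points, 5 per tissue, coloured by tissue) of the 12 leading enriched genes of brain, heart and liver in 3 panels, with the genes in rows. Clec4g lies at 12.54 in liver and near 5.1 in the other tissues, whereas the sarcomere gene Actc1 (SD 1.252) and Fabp9 (SD 1.90) spread widely over the heart arrays and Meox2 (SD 0.05) does not.

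Of 12 genes of sinusoidal endocytosis 10 were enriched in liver, with a mean of 10.3 ± 0.11 against 6.32 ± 0.07 in brain and 6.42 ± 0.07 in heart (camera adjusted p = 1.05e-18, 6.56e-05 with an estimated correlation). Of 16 genes of sinusoidal identity 15 were enriched, with a mean of 9.91 ± 0.15 against 5.62 ± 0.05 and 5.84 ± 0.02 (camera adjusted p = 2e-26, 1.81e-05 with an estimated correlation). Both counts were the same adjusted over the list alone. Gata4, a transcription factor of this list, was at 9.03 ± 0.19 in liver against 6.30 ± 0.15 in brain and 6.66 ± 0.14 in heart, 5.19-fold higher (adjusted p = 6.61e-12). The transcription factor list as a whole was lower in liver (camera adjusted p = 6.58e-05, 0.0241 with an estimated correlation), with 6 of 29 members lower and 4 higher (8 and 4 adjusted over the list alone). Tbx3 was 6.29-fold lower and Hoxb5 was 5.06-fold higher.

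Of 21 Notch and arterial genes 14 were lower in liver than in both other tissues and 1 higher, over all genes and adjusted over the list alone (camera adjusted p = 1.87e-10, and adjusted p = 0.0601 with an estimated correlation). Stmn2 was 15.2-fold lower, the Notch target Hey1 10.1-fold and Mgp 6.75-fold. Basement membrane genes were lower too (8 of 16 lower and 0 higher, 10 and 0 adjusted over the list alone, camera adjusted p = 2.08e-06), with the call lost at adjusted p = 0.122 with an estimated correlation. The leading depleted genes of liver were the carbonic anhydrase Car4 at 5.21 ± 0.10 against 11.90 ± 0.09 in brain and 10.46 ± 0.25 in heart (38.1-fold lower, adjusted p = 1.61e-16 against heart), the transcription factor Ebf1 (36.8-fold), the matrix protein Sparcl1 (34.2-fold), Rassf9 (34-fold), Palmd (26-fold) and the drug efflux pump Abcb1a (25.1-fold). Barrier transporters were lower in liver in 13 of 24 cases and higher in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 2.51e-23, 0.00106 with an estimated correlation). In heart 3 of the 24 were lower than in both other tissues (camera adjusted p = 1.45e-16, 0.00311 with an estimated correlation). Tight junction genes (2 of 14 lower, camera adjusted p = 0.00174) and Wnt and norrin genes (2 of 16 lower and 1 higher, 3 and 2 adjusted over the list alone, camera adjusted p = 4.59e-05) were called lower in liver, both with adjusted p = 0.0537 with an estimated correlation. Caveolar genes were split, with 4 of 9 lower and 2 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0196, lower; adjusted p = 0.0766 with an estimated correlation), Aqp1 being 2.21-fold higher than in heart. In heart, Wnt and norrin genes were lower (3 of 16 lower than in both, 4 adjusted over the list alone; camera adjusted p = 3.2e-12, 0.0029 with an estimated correlation). The sinusoidal lists were lower in brain and heart (camera adjusted p-values from 6.79e-23 to 8.05e-17), with 1 of 12 (2 adjusted over the list alone) and 5 of 16 members lower than in both other tissues in brain and 2 of 12 and 3 of 16 in heart.

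Respiratory chain genes were higher in liver (4 of 20 higher, 0 lower; 6 adjusted over the list alone; camera adjusted p = 0.000304), a call lost with an estimated correlation (adjusted p = 0.24). Ndufa9 was 1.35-fold and Cox5b 1.22-fold higher, the latter not passing after a new quantile normalization (adjusted p = 0.181). Of 12 antigen presentation genes 4 were higher in liver, among them H2-Aa (4.53-fold, 8.19 ± 1.34 in liver) and Cd74 (3.70-fold, 7.33 ± 1.31). The list's camera adjusted p was 0.02, with adjusted p = 0.198 with an estimated correlation and 0.193 after the filter on dim genes. Immediate-early and heat shock genes, which respond within minutes to handling and heat, were lower in liver in 10 of 24 cases and higher in 0 over all genes, and in 10 and 1 adjusted over the list alone. The small heat shock protein Hspb1 was 11-fold lower at 6.96 ± 0.46, Nr4a1 3.03-fold and Klf4 2.87-fold. The list's camera adjusted p was 6.86e-05 in liver, with adjusted p = 0.41 with an estimated correlation. It was called higher in brain (camera adjusted p = 3.33e-05, adjusted p = 0.465 with an estimated correlation), where 1 member passed against both tissues (0 adjusted over the list alone).

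Markers of other cell types moved with the liver group as well. Of 7 Kupffer cell markers, all 7 were higher in liver and 5 enriched (camera adjusted p = 0.000333, and adjusted p = 0.286 with an estimated correlation), with Vsig4 at 8.88 ± 2.39 and Clec4f at 8.21 ± 1.59 in liver. The list's mean was 7.57, 8.29 and 7.91 in liver replicates 1, 3 and 4 and 5.75 and 5.46 in replicates 2 and 5, against at most 5.00 in any brain or heart array. Of 15 macrophage markers 7 were higher (camera adjusted p = 0.00142, and adjusted p = 0.402 with an estimated correlation), led by Lyz2 (4.58-fold) and Aif1 (4.87-fold). The antigen presentation genes above followed the same arrays, with a list mean of 7.86 ± 0.29 in liver. Of 17 hepatocyte markers 13 were higher (14 adjusted over the list alone; camera adjusted p = 1.81e-12, 0.00261 with an estimated correlation), with Alb at 9.88 ± 0.37 against 4.19 ± 0.07 in brain and 4.25 ± 0.19 in heart, and Apoa2 at 9.91 ± 0.91. Without liver replicates 1, 3 and 4, 446 genes were enriched in liver, of which 426 were among the 536. The Kupffer cell list was still called by camera then (mean difference 0.72, adjusted p = 0.00319). So was the antigen presentation list (mean difference 0.35 against 0.64 with all arrays, camera adjusted p = 0.0159). The macrophage list was not (0.19, camera adjusted p = 0.216). Of the Kupffer cell and macrophage lists 1 marker was enriched, against 12 with all arrays. A fall in these markers follows from leaving out the arrays where they were highest.

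**Figure D3:**
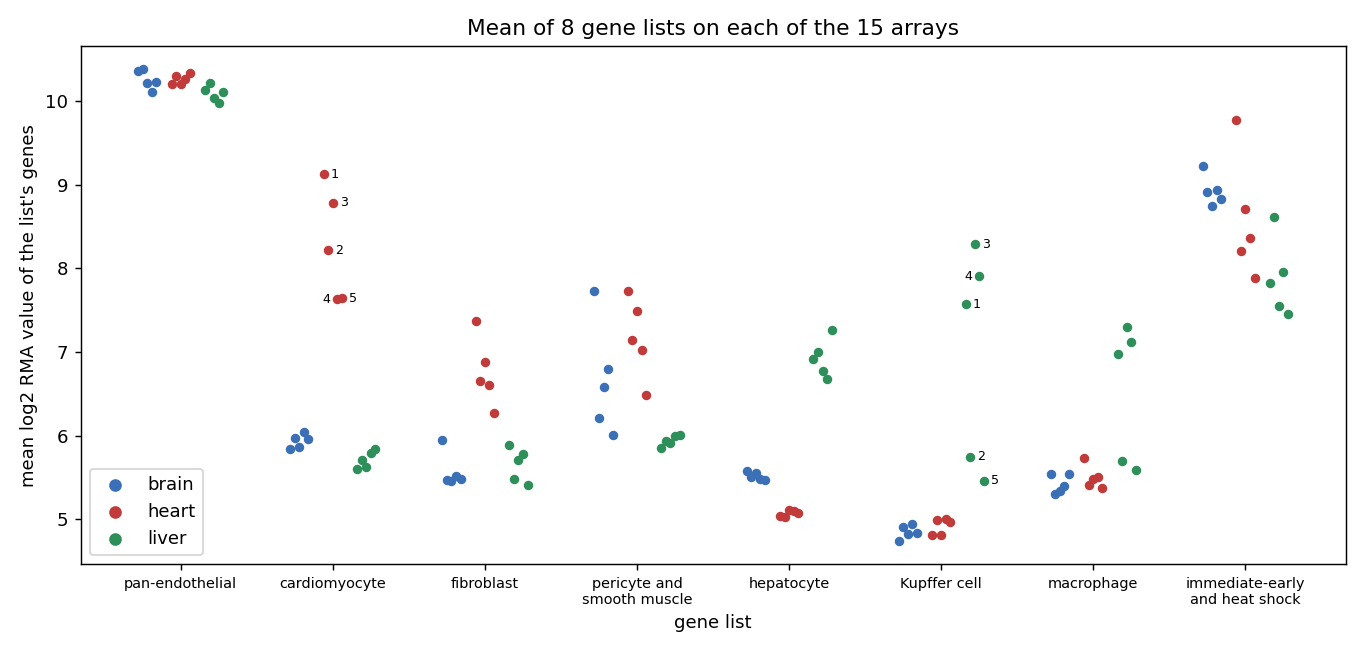
Mean log2 RMA value of the genes of 8 lists (horizontal axis) on each of the 15 arrays, coloured by tissue; small numbers give the replicate for the cardiomyocyte list in heart and the Kupffer cell list in liver. The pan-endothelial means lie between 9.98 and 10.4 on all arrays, while the cardiomyocyte means of the heart arrays range from 7.63 to 9.12 and the Kupffer cell means of the liver arrays from 5.46 to 8.29.

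In the pairwise comparisons, 3070 of 19938 genes (15.4%) differed between brain and heart, 5003 (25.1%) between brain and liver and 5538 (27.8%) between heart and liver. At a log2 difference of 1 or more the counts were 769, 1472 and 1298. Between brain and heart, 1652 genes were higher in brain and 1418 higher in heart. The largest differences toward brain were Ttr (log2 7.16, SE 0.30), Slco1c1 (6.87) and Slco1a4 (6.86), and toward heart Cd36 (log2 -8.25 for brain minus heart, SE 0.14), Myl2 (-6.05) and Fabp4 (-5.68). Between brain and liver, 2204 genes were higher in brain, led by Itm2a (log2 7.58, SE 0.14), Slco1c1 (7.36) and Slco1a4 (7.19), and 2799 higher in liver, led by Msr1 (-7.61 for brain minus liver, SE 0.09), Clec4g (-7.40) and Mrc1 (-7.35). Between heart and liver, 2286 genes were higher in heart, led by Myl2 (log2 6.07, SE 0.24), Rassf9 (5.40) and the apelin receptor Aplnr (5.39), and 3252 higher in liver, led by Clec4g (-7.42 for heart minus liver, SE 0.11), Dnase1l3 (-7.31) and Il1a (-7.15).

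The share of called genes that were higher in the first tissue depended on the scaling. Liver held the majority against brain and against heart as deposited and under the 3 other scalings, though barely after a new quantile normalization. Between brain and heart the majority changed side, so it is not settled by these values. For brain against liver the share was 44.1% as deposited, 38.4% after median centring, 22.2% after centring on the pan-endothelial list and 48.2% after a new quantile normalization. For heart against liver it was 41.3%, 32.5%, 18.9% and 49.6% in the same order, and for brain against heart 53.8%, 57.5%, 57.7% and 48.9%. Centring on the pan-endothelial list moved the median difference of all genes by -0.16 for brain minus liver and by -0.17 for heart minus liver. None of the 22 list results and 126 named gene results followed through the alternatives changed its direction under any of the 3 other scalings. Not every called list described above was among the 22.

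The remaining list results were these. In brain, markers of Kupffer cells, hepatocytes, stellate cells and cardiomyocytes were called lower (camera adjusted p-values of 0.02, 3.86e-06, 0.0237 and 9.65e-06). Lower than in both other tissues were 0 of 7, 1 of 17, 0 of 9 and 0 of 16 members, and 1 hepatocyte marker was higher. The hepatocyte list's mean was 5.52 in brain, above heart (5.07) and below liver (6.925), so that list was lower only against liver. Only the hepatocyte call held with an estimated correlation (adjusted p = 0.0316, against 0.477, 0.3 and 0.361 for the others). In heart, markers of Kupffer cells (adjusted p = 0.0263, and adjusted p = 0.579 with an estimated correlation) and hepatocytes (5.2e-10, and 0.00476 with an estimated correlation) were called lower. Of their members 0 of 7 and 3 of 17 were lower than in both other tissues. In liver, markers of cardiomyocytes, fibroblasts and of pericytes and smooth muscle were called lower (8.85e-08, 0.00405 and 0.000925), with adjusted p-values of 0.24, 0.286 and 0.402 with an estimated correlation. There 1 of 16, 1 of 11 and 5 of 14 members were lower than in both (the last 6 adjusted over the list alone). The other 12 lists passed in none of the 3 tissues: pan-endothelial, glycolysis, haemostasis, venous and lymphatic, VEGF and angiopoietin, and the markers of neurons, astrocytes, oligodendrocytes, lymphoid cells, granulocytes, red cells and platelets, with a smallest adjusted p of 0.0646 (lymphoid markers, in brain). Although the lymphoid list did not pass, 3 of its 11 markers were higher in liver than in both other tissues, 2 of them enriched. Of the 17, 16 and 18 lists called in brain, heart and liver, 7, 7 and 5 held with an estimated correlation. A list's median, mean and test differed in sign for 1, 8 and 5 of the 36 lists in the 3 tissues, none of them called.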

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

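Of the tests in this part, those of the scaling, of the joint movement of the macrophage and Kupffer cell markers and of the digestion temperature were chosen after the results were seen. In 402 groups of 5 arrays (115 named genes and 19 described lists in each tissue), 28 had an array set apart from the other 4 by Dixon's ratio of the gap to the range. Chance gives about 1 in 20 groups, or 20.1 of 402.

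Among the brain arrays, replicate 1 stood apart with high fibroblast markers (list mean 5.95 against 5.48 for the others, ratio 0.866), Lum (ratio 0.847), Postn (0.759) and Il1a (0.770) and with low Gpihbp1 (0.732). Lpl was low in brain replicate 2 (ratio 0.753), Cd74 high in brain replicate 3 (0.725) and Cav1 low in brain replicate 4 (0.795). Among the heart arrays, replicate 1 was high for Il1a (0.724), Akr1b8 (0.717), C1qc (0.806) and Foxf1 (0.710006, 6.89 against 6.26 for the others, just over the limit). Heart replicate 2 was high for Car8 (0.787), Cav1 (0.827) and Cd163 (0.770) and low for Cgnl1 (0.711). Heart replicate 3 was high for Foxq1 (0.796) and low for the tight junction list (0.759). Heart replicate 4 was low for Abcb1a (0.712), and heart replicate 5 was low for Slc39a8 (0.737) and high for the antigen presentation list (0.714). Among the liver arrays, replicate 5 was high for Ttr (9.98 against 8.06, ratio 0.887) and low for Ablim3 (0.752). Liver replicate 1 was low for Msr1 (0.744) and high for Hoxb5 (0.715). Fabp4 was high in liver replicate 2 (0.718), Rassf9 low in liver replicate 3 (0.722) and Actc1 high in liver replicate 4 (0.804).

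Cardiomyocyte transcripts were high in the heart arrays although the cells had been sorted for GFP. If RNA of cardiomyocytes came into the sorted samples, the markers should move together from array to array. The 15 called markers had a mean pairwise correlation of 0.888 over the 5 heart arrays, against a median of 0.06 and a 95th percentile of 0.26 for 1000 random sets of other heart-enriched genes, so such RNA is a candidate explanation for the markers, led by Tnnt2 at 11.36, Myl2 at 10.49 and Actc1 at 10.34. For the 170 other heart-enriched genes as a set the tables argue against it, since their slope on the marker score had a median of 0.123 (0.10 to 0.13 when single arrays were left out), where cardiomyocyte RNA would give a slope near 1; the bound set beforehand, an upper quartile under 0.5, was met on all 5 arrays (0.44) but not in every run without a single array (up to 0.56), so this rests on the median. In 38 of the 170 genes the slope was over 0.5, and for those cardiomyocyte RNA stays open. The 38 include the 4 enriched fibroblast markers and the 3 enriched pericyte and smooth muscle markers. The slope therefore does not tell cardiomyocyte RNA from RNA of those cells. The markers' mean difference was at least 2.36 under the 3 other scalings, against 2.45 as deposited. Those scalings moved the median difference of all genes by -0.17 at the most, too little to remove it. The scaling check shows only that the difference does not rest on the choice among these scalings. It tested no biological explanation.

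Macrophage and Kupffer cell transcripts differed strongly among the liver arrays. The 14 called markers had a mean pairwise correlation of 0.912 over the 5 liver arrays, against a median of 0.09 and a 95th percentile of 0.27 for 1000 random sets of other liver-enriched genes. The list means had already shown these markers moving together, so this correlation adds no evidence, and RNA of such cells in some of the sorted liver samples stays open for the markers, with Vsig4 at 8.88, Clec4f at 8.21 and Aif1 at 7.98; 0 of the 7 Kupffer cell markers stood on another list and 0 lay above the median of all values in brain or heart. The 524 other liver-enriched genes as a set did not follow them, with a median slope of 0.039 on the Kupffer cell score (0.02 to 0.06 when single arrays were left out) and an upper quartile of 0.14, although 40 had slopes over 0.5. The 524 include the 8 enriched hepatocyte markers, Alb and Apoa2 among them. The Kupffer cell score does not bear on RNA of hepatocytes, which was not tested as a source. The Kupffer cell list's smallest mean difference under the 3 other scalings was 2.09, against 2.11 as deposited. Those scalings moved the median difference of all genes by -0.17 at the most, too little to remove it. The scaling check shows only that the difference does not rest on the choice among these scalings. It tested no biological explanation.

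Immediate-early and heat shock genes were lower in liver, the tissue digested at room temperature. The array means of the list were 8.93 in brain, 8.59 in heart and 7.88 in liver, with exact two-sided permutation p-values (252 splits of 10 arrays, smallest possible p 0.0079) of 0.00794 for brain against liver, 0.0794 for heart against liver and 0.341 for brain against heart, and 0.0238, 0.119 and 0.341 after Benjamini-Hochberg adjustment over the 3. Were the temperature the cause, brain and heart, both digested at 37 °C, were taken to be alike, although they also differed in tissue and treatment. Their median difference over the list was 0.258. The difference of their array means was 0.338, with a standard error of 0.335. Temperature, enzyme and tissue therefore cannot be told apart here. The list's mean difference in liver was -0.71 under the scaling that reduced it most, against -0.88 as deposited. The other scalings moved the median difference of all genes by -0.17 at the most, too little to remove it. This shows only that the difference does not rest on the choice among these scalings.

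The counts of genes were set against other groupings of the same arrays, 100 splits with the real one included. The real split was the 1 split with the largest count for every gene count. It gave 3070 genes against at most 30 for brain and heart and 5003 against at most 1 for brain and liver. For heart and liver it gave 5538 against at most 9. The other splits gave at most 0 against each of 311, 181 and 536 enriched and 130, 62 and 292 depleted genes. This argues against a random division of the arrays as the source of the counts. A split that mixes tissues puts the tissue differences into the spread within its groups, which keeps its count low. The splits therefore do not bear on single genes, nor do they tell tissue from enzyme, digestion temperature or pool size. For the number of lists called by camera with the preset correlation, 3 of 100 splits reached the 17 of brain (highest other 17). For liver 2 of 100 reached the 18 (highest other 18). Other splits thus gave the same counts. A split that mixes tissues unevenly still holds part of a tissue difference between its groups, so these list counts do not settle chance for brain or liver. For the 16 lists of heart 8 of 100 splits reached that number (highest other 20), so chance stays open for that count.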

How the results depend on the processing

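The without-several-arrays settings and the setting without other-cell markers were chosen after seeing the data. Under the alternatives the 12 counts took 339 values in all, of which 321 stayed within 1.5 times the count reported. Leaving out single arrays gave 2675 to 3138 genes for brain versus heart, 4495 to 5164 for brain versus liver and 4798 to 5633 for heart versus liver. It gave 298 to 320 brain-enriched, 164 to 195 heart-enriched and 495 to 575 liver-enriched genes, 126 to 137 brain-depleted, 57 to 72 heart-depleted and 285 to 301 liver-depleted genes, and 15 to 19, 15 to 18 and 18 to 19 lists called in brain, heart and liver. Counts moved where the threshold itself moved: at an adjusted p under 0.01 brain versus heart gave 2043 genes. With a log2 difference of 2 or more the enriched genes were 113 in brain, 47 in heart and 164 in liver and the depleted genes 31, 12 and 94; with no limit they were 937, 743 and 2064 enriched and 563, 651 and 1124 depleted. With an estimated correlation, camera called 7 lists in brain, 7 in heart and 5 in liver, and fry called 28 in brain. Without liver replicates 1, 3 and 4, heart versus liver gave 3285 genes, from fewer arrays. The replicate numbers were not used to pair the arrays, since no label says that a number was shared and same-numbered pools held different numbers of mice. Of 15 pairs of same-numbered arrays, 6 had a correlation of deviations from the tissue means over 0.1 (range -0.001 to 0.20). The median was 0.095 for same-numbered pairs and -0.024 for the others, and 8 of 15 arrays correlated best with their own number in both other tissues. Replicates 1 and 5 also held the lowest and highest scores on the third principal component in every tissue. Both are signs, from the data and not the design, that arrays of a number shared something the labels do not name. The fit with the replicate block gave 3369, 5282 and 5936 genes in the 3 comparisons in the order above, 311, 182 and 539 enriched and 131, 62 and 293 depleted genes, and 20, 17 and 18 lists. Without the members of other-cell lists, 308, 163 and 512 genes were enriched. Of 594 values for 22 of the list results 16 and of 2894 for named genes 63 crossed the threshold, and none reversed. The genes were mainly Cdh5, Dcn, Egr2, Gkn3 in liver, Mgp in brain and Ndufs8 (toward no call) and Foxf1 and Top2a (toward a call). The causes were not tested.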

Other observations

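The test of choroid plexus markers below used a list written after Ttr had been seen and before its other members were looked at.

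Haemostasis genes went both ways in brain and liver, which the list test does not show. Of 14 measured members, 5 were higher in brain than in both other tissues and 3 lower, 0 were higher in heart and 1 lower, and 3 were higher in liver and 5 lower, F8 being the largest at 50.4-fold higher in liver. Venous and lymphatic genes were similar, with 2 of 11 higher and 3 lower in brain (2 and 4 adjusted over the list alone), 1 and 2 in heart and 5 and 1 in liver. Of the 17 VEGF and angiopoietin genes, 2 were higher and 3 lower in brain (3 and 3 adjusted over the list alone), 3 and 2 in heart (4 and 2 adjusted over the list alone) and 5 and 3 in liver. Of the 12 glycolysis genes, 2 were higher and 0 lower in brain (3 and 0 adjusted over the list alone), 0 and 1 in heart (1 and 2 adjusted over the list alone) and 1 and 1 in liver. These 4 lists did not pass camera in any tissue.

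Probe sets left out of the comparisons also separated the tissues when fitted in the same way with limma. Of 12146 probe sets unnamed here, 35 were enriched in brain, 71 in heart and 100 in liver, and 17, 4 and 83 were depleted. Of 1621 probe sets with several gene symbols, 9, 24 and 21 were enriched and 6, 0 and 4 depleted.

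Ttr, on the hepatocyte list, was 16.5-fold higher in brain than in liver and higher by a log2 difference of 7.16 than in heart. A candidate explanation is RNA of the choroid plexus epithelium, which makes large amounts of Ttr, in the sorted brain samples; the GFP sort would be meant to remove it. Of 14 other measured markers of that epithelium, 3 (Kl, Clic6 and F5, named after their values were seen) were enriched in brain, or 21.4%. Without a limit on the difference, 6 were higher in brain than in both other tissues. Over all 19938 genes, 311 were enriched in brain and 937 higher than in both. The explanation needed more than 50% of the markers to be enriched, and at most 25% would have argued against it. The 21.4% fell on the side against it. The markers were read on the same brain arrays and may vary together, so this share has no valid interval here. The share of markers higher than in both tissues, 6 of 14 against 937 of 19938 genes, goes with the explanation. The values thus point both ways, and the explanation stays open. Expression of Ttr by brain endothelial cells themselves was not tested and stays open as well.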
